A study of Drosophila simulans and Drosophila sechellia and Drosophila yakuba with 4 samples.

How the data were processed

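Small RNAs were measured in 4 libraries, 1 from male bodies of each of D. simulans, D. sechellia, D. yakuba and D. erecta. Per the labels' protocols, frozen flies were vortexed so that heads came off, bodies were collected on a 0.600 mm sieve, and RNA was extracted with TRIzol. The same text describes a pair of cloning protocols for every sample. In one an 18 to 26 nt fraction was cut from a gel and ligated to adapters that need a 5′ phosphate and a 3′ hydroxyl, for the GAII sequencer. In the other an 18 to 29 nt fraction was cloned with a modified TruSeq kit, with a second gel purification after ligation, for the HiSeq. Which library was made with which protocol is not given in the sources used here. That matters because adapter ligation favours some sequences over others, and a difference in protocol would then appear as a difference between species.

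The deposited tables give, for each distinct sequence, its raw read count, and this unit was read from the values: whole numbers of at least 1 that sum to a different total in each table. Adapters had been removed and identical reads collapsed by the authors, as the deposited sequences of variable length show. Adapter trimmer, quality filter, aligner and genome build are not given in the sources used here, and the tables hold neither gene names nor positions. Sequences ran from 18 to 30 nt, and to 29 nt in D. simulans. There were no molecular identifiers, so copies made by amplification are counted as reads, and intervals cover counting error only.

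No genome of these species was used, so small RNAs were named from a list of 132 published D. melanogaster sequences written from general knowledge before the data were examined. The list held 127 mature miRNAs, the hairpin siRNA esi-2.1, 1 Suppressor of Stellate piRNA, 2S ribosomal RNA and the 5′ fragments of tRNA-Gly and tRNA-Glu. The miRNAs were grouped as somatic, further passenger and 5′ arms, muscle, let-7 cluster, miR-277 cluster, K-box, miR-92, early embryo, neural, ovary, mirtron and 5 testis clusters with 24 members. A read was assigned to an entry when it held bases 2 to 19 of it exactly, starting at read position 1, 2 or 3. Members that differ by 1 base within that stretch (miR-276a and miR-276b, miR-13a and miR-13b, miR-31a and miR-31b, miR-281-1 and miR-281-2) can exchange reads through sequencing error, and a list entry recalled wrongly, or a miRNA that differs in sequence in these species, would lose reads. Differences between the 4 libraries at a listed sequence do not depend on how it is named.

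Levels are reads per 1000000 listed miRNA reads (RPM), and log2 ratios used a pseudocount of 0.5 read. With 1 library per species no test was run and no p-value is given. A miRNA counted as different at 2-fold or more, among those with at least 100 reads in a library of the contrast. A library with 0 reads was set to a floor of 3 reads, the one-sided 95% limit of a count of 0, where a limit or a value at the floor is given; the exact intervals are two-sided and reach further. The 3 contrasts were D. sechellia over D. simulans, D. erecta over D. yakuba, and the mean log2 level of D. yakuba and D. erecta over that of D. simulans and D. sechellia. A list's median was placed among the medians of 10000 random lists of the same size, drawn from the measured miRNAs of the contrast in 4 bins of mean level; that percentile describes these libraries. The named miRNAs were, by a rule fixed at the same time as the list, the 8 highest and 8 lowest ratios of each contrast past 2-fold and 100 reads, the 5 most abundant of each library, up to 4 examples for each list, the tissue markers, and the 5 most abundant unlisted sequences by length and count. The miRNAs named for their substitutions, and the clusters compared with up to 3 mismatches, were chosen after their values were seen.

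Length classes were 18 to 20, 21, 22 to 23, 24 to 29 and 30 nt. For the siRNA signature, 21 nt reads outside the list were scored when their first 19 bases were the reverse complement of the first 19 of another such read. Bases 1 and 10 were counted in reads of 24 to 29 nt outside the list. For sharing between species every library was thinned, by a seeded draw without replacement, to the 21286502 reads of the smallest. Alternatives covered the denominator, TMM and DESeq2 scaling, the 5′ start, 1 mismatch in bases 9 to 19 with the seed (bases 2 to 8) exact, a shorter core, the read minimum, the pseudocount, distinct sequences in place of reads, leaving out sequences read once, length limits and thinning. Alternatives added after the data were examined were a contrast without D. simulans, a wider 5′ shift, a denominator without 2S fragments, up to 3 mismatches with shuffled control sequences, thinned 21 nt reads, sharing without listed RNAs, sequences found in none of the other libraries, and the share at each length without 2S and listed tRNA fragments.

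The steps were tested on simulated data. In counts drawn for D. sechellia over D. simulans at the real totals, with 85 miRNAs past the read minimum, all 15 miRNAs made 4-fold higher, all 14 made 4-fold lower and all 56 left unchanged fell on the right side of the 2-fold rule. These draws held counting noise only, so they check how the rule is applied and not variation between libraries or preparations. Simulated reads with 3 substitutions were given the right name in 96.8% of 1005 cases and a wrong one in 1.19%, and 0.005% of 20000 random sequences received a name. Analyses were run with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and scaling factors with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. The labels' reference table of D. simulans gene names holds no miRNA and was not used.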

Results

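Small RNAs were sequenced from headless male bodies, that is thorax and abdomen, of 4 fly species closely related to Drosophila melanogaster. D. simulans and D. sechellia are sister species, and D. yakuba and D. erecta lie on another branch of the group. Each species gave 1 library, so no difference given here has a replicate check, and every ratio compares libraries. The libraries held 21286502 reads in D. simulans, 31511504 in D. sechellia, 32356375 in D. yakuba and 27482313 in D. erecta. Distinct sequences numbered 1177942, 1724857, 1864761 and 1515579, and 72.6% to 77.3% of them were read once. Reads of the 127 listed microRNAs (miRNAs, short regulators cut from hairpin transcripts) made up 32.5%, 34.8%, 11.2% and 39.8% of the reads, in the same species order. Fragments of 2S ribosomal RNA, a 30 nt RNA of flies, took 2.62%, 5.33%, 25.2% and 7.73%. Levels are in reads per 1000000 listed miRNA reads (RPM). Intervals are exact Poisson intervals for counts and ratios and Wilson intervals for shares, at 95%, and cover counting error only.

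The miRNAs that filled male bodies were the same few in D. sechellia, D. yakuba and D. erecta, and a different set led in D. simulans. In those first 3 libraries miR-8-3p, which is broadly expressed in flies, came first at 31.2%, 28.7% and 28.8% of listed miRNA reads. The muscle miRNA miR-1-3p came second at 17.6%, 20.9% and 13.7%, and miR-34-5p and the growth regulator bantam-3p took the next places. The fifth place went to miR-276a-5p in D. sechellia (8.66%) and D. yakuba (3.98%), and to miR-277-3p in D. erecta (4.69%). In D. simulans miR-956-3p led with 33.6%, followed by miR-8-3p at 19.8%, miR-281-2-5p at 8.11%, miR-317-3p at 6.35% and bantam-3p at 6.02%. The 5 leading miRNAs together took 73.9%, 76.3%, 75.1% and 71.6% in D. simulans, D. sechellia, D. yakuba and D. erecta. Across the 97 miRNAs with at least 100 reads in some library, log2 levels correlated at Pearson r = 0.905 between D. sechellia and D. yakuba, 0.866 between D. sechellia and D. erecta, and 0.951 between D. yakuba and D. erecta. The D. simulans library correlated with them at 0.583, 0.544 and 0.522, with D. sechellia first; Spearman's rho was 0.614, 0.582 and 0.606. These correlations run across miRNAs, which are not independent replicates.

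**Figure D1:**
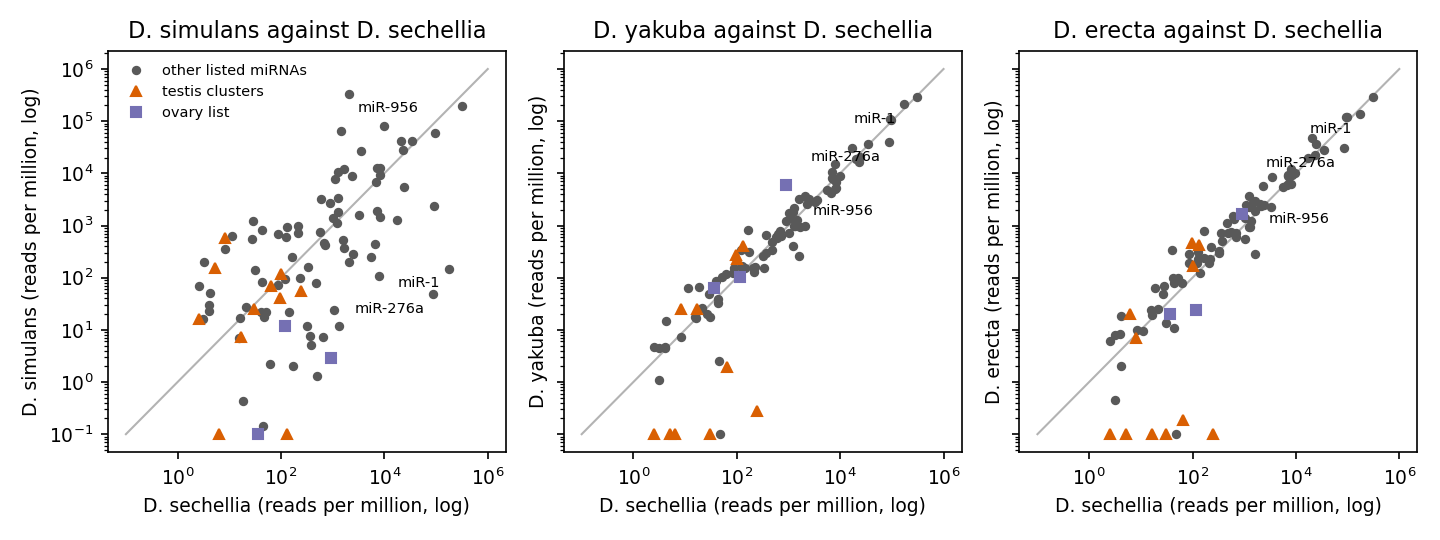
Levels of the listed miRNAs with at least 100 reads in some library, in RPM on log axes, in D. simulans, D. yakuba and D. erecta (vertical axes) against D. sechellia (horizontal axes), 1 point per miRNA; triangles are testis clusters, squares the ovary list, the line marks equal levels, and levels under 0.1 are drawn at 0.1. Points scatter widely for D. simulans (r = 0.583) and lie near the line for D. yakuba (r = 0.905) and D. erecta (r = 0.866), apart from several testis-cluster miRNAs.

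The first comparison set D. sechellia against its sister species D. simulans. The muscle miRNA miR-1-3p stood at 175550 RPM in D. sechellia and 149 in D. simulans, a 1176-fold difference (1106 to 1251), while the other muscle miRNA, miR-133-3p, was 2.99-fold higher (2.88 to 3.10). The 5′ arm miR-276a-5p was 1821-fold higher in D. sechellia (1634 to 2035), and miR-276a-3p, from the other arm of the same hairpin, had a log2 ratio of -2.92. In the other direction miR-956-3p was 163-fold lower in D. sechellia (160.5 to 165), at 2064 against 335728 RPM. Of 96 miRNAs with at least 100 reads in either library, 40 were at least 2-fold higher in D. sechellia, 32 at least 2-fold lower and 24 in between; with DESeq2 size factors, which moved the median of all by -0.25, 33 were higher and 34 lower, and with TMM scaling, which moved it by 0.34, 43 and 31. The 8 highest ratios also held miR-79-3p (377-fold, 9 exact reads in D. simulans and 80 more with A10C and A16G), the ovary miRNA miR-989-3p (316-fold, from 2.89 to 914 RPM), miR-929-5p (308-fold, 1 read in D. simulans, interval 55.1 to 12203.5) and miR-263b-5p (111-fold), a sensory-organ miRNA. A further pair had no exact read in D. simulans: against a floor of 3 reads miR-974-5p of the testis clusters was 302-fold higher (lower limit of the exact interval 245) and the ovary miRNA miR-994-5p 83.02-fold higher (67.2). With 1 mismatch allowed, miR-974-5p had 39 reads in D. simulans, all with substitution A17G; such positions are counted from 1 at the 5′ end of the listed mature miRNA. The lowest ratios after miR-956-3p were those of miR-311-3p (69.6-fold lower, testis cluster), miR-286-3p (63.7-fold, early embryo), miR-92b-3p (55.8-fold), miR-317-3p (44.0-fold), miR-190-5p (43.0-fold), miR-278-3p (42.8-fold) and miR-976-3p (28.9-fold, testis cluster).

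By list, members of one group often went opposite ways between D. sechellia and D. simulans. Of the miR-2 and miR-13 seed family with miR-11 and miR-308 (the K-box list), 4 of 6 members were at least 2-fold higher in D. sechellia and miR-308-3p lower, with a median log2 ratio of 4.11 at the 97.5 percentile of random lists; miR-2a-3p was 74.4-fold higher. All 3 ovary miRNAs were higher (median 8.27, or 6.38 with libraries at 0 reads set to 3 reads, percentile 99.2). Of 6 measured neural miRNAs, 4 were higher, among them miR-124-3p (47.02-fold) and miR-7-5p (71.9-fold), and miR-315-5p was lower (log2 ratio -2.19). In the miR-277 cluster, whose 3 miRNAs come from 1 transcript, miR-34-5p was 37.98-fold higher while miR-317-3p and miR-277-3p had log2 ratios of -5.46 and -1.03. In the let-7 cluster, which times development and adult maturation, let-7-5p was 4.36-fold higher, miR-125-5p had a log2 ratio of 1.01 and miR-100-5p of 0.22. Of the 4 further passenger and 5′ arms, 3 were higher and miR-281-2-5p lower (log2 ratio -3.06). Of 52 measured members of the general somatic list, 15 were higher, 20 lower and 17 in between, with a median of -0.33 at the 1.905 percentile, of 0.0048 with TMM scaling and of -0.58 with DESeq2 size factors. Both measured early-embryo miRNAs, miR-286-3p and miR-5-5p, and the 1 measured miR-92 member were lower, and of 4 mirtrons (miRNAs spliced out as whole introns) 2 were higher and 1 lower. With DESeq2 size factors 2 of the further arms, 1 of the let-7 cluster and 1 of the mirtrons were higher.

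Between D. erecta and D. yakuba, by contrast, most miRNAs lay within 2-fold. The highest ratio with reads in both was that of miR-274-5p, 5.57-fold higher in D. erecta (5.28 to 5.87), followed by miR-929-5p (4.28-fold, 2.18 to 9.603), miR-282-5p (4.04-fold), miR-12-5p (3.67-fold), the neural miRNA miR-1000-5p (3.31-fold), miR-276a-3p (2.71-fold) and miR-305-5p (2.63-fold). The lowest were miR-92b-3p (6.50-fold lower), the ovary miRNAs miR-318-3p (4.30-fold), miR-989-3p (3.55-fold, 3.48 to 3.62) and miR-994-5p (3.24-fold), and miR-999-3p (2.35-fold). Of 84 measured miRNAs, 21 were at least 2-fold higher in D. erecta, 5 lower and 58 in between; DESeq2 size factors, which moved the median of all by -0.29, gave 11 and 7. Per all reads in the library, 78 were higher and none of the 84 lower, since listed miRNAs took 39.8% of the D. erecta reads and 11.2% of those of D. yakuba, and the median of all miRNAs moved by 1.82 on the log2 scale; miR-994-5p and miR-999-3p then had log2 ratios of 0.13 and 0.59. The testis-cluster miRNA miR-960-5p was 24.2-fold higher by exact match against the floor of 3 reads (lower limit of the exact interval 19.5), but its log2 ratio was -0.63 with 1 mismatch allowed, where D. yakuba reads carried A11U.

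The ovary list was the most uniform between D. erecta and D. yakuba, with all 3 members lower in D. erecta (median log2 ratio -1.83, percentile 0.795; -0.0018 per all reads, where none was past 2-fold). Of the somatic list 15 of 50 measured members were higher and 1 lower (median 0.39, percentile 96.7), against 8 and 2 (0.096) with DESeq2 size factors and 48 and 0 (2.22) per all reads. Of the miR-277 cluster miR-277-3p and miR-317-3p were higher (1 of them with DESeq2 size factors) and miR-34-5p had a ratio of 0.14. Of 6 measured neural miRNAs miR-1000-5p and miR-124-3p were higher (median -0.21), or 1 of them with DESeq2 size factors. All 6 K-box miRNAs, both muscle miRNAs, the 4 further arms and the 2 measured mirtrons lay within 2-fold, with medians of -0.23, -0.35, -0.08 and -0.20; per all reads these medians, and that of the neural list, were positive at 1.59, 1.48, 1.74, 1.62 and 1.62. With DESeq2 size factors 1 of the mirtrons was lower. The 1 measured miR-92 member, miR-92b-3p, was lower, but under 2-fold per all reads (-0.87). Of the let-7 cluster miR-125-5p was higher (log2 ratio 1.04, under 2-fold with TMM scaling and DESeq2 size factors), and no early-embryo miRNA reached 100 reads.

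The third comparison set D. yakuba and D. erecta against D. simulans and D. sechellia, as mean log2 levels. The 8 highest mean log2 ratios were those of the testis-cluster miRNA miR-974-5p (7.07, or 5.77 with D. simulans at the floor of 3 reads), the ovary miRNA miR-989-3p (5.90), the muscle miRNA miR-1-3p (5.05), miR-79-3p (4.50), miR-994-5p (4.48, or 3.18 at the floor), miR-285-3p (4.41), miR-276a-5p (4.09) and miR-2a-3p (3.88). With up to 3 mismatches miR-974-5p stood at 5.64 RPM in D. simulans, 138 in D. sechellia, 422 in D. yakuba and 429 in D. erecta, a smaller difference than at the floor. Against D. sechellia alone, a contrast chosen after the data were examined, miR-1-3p stood at -0.05, miR-994-5p at -0.0033, miR-276a-5p at -1.32, miR-79-3p at 0.25 and miR-2a-3p at 0.78, while miR-974-5p, miR-989-3p and miR-285-3p stood at 1.65, 1.77 and 1.80. Of the 8 lowest 5 were testis-cluster miRNAs, of which miR-976-3p, miR-963-5p and miR-310-3p had no exact read in D. yakuba or D. erecta and miR-962-5p had 1 in D. yakuba. With libraries at 0 set to 3 reads, their mean log2 ratios were -5.87, -5.85, -3.76 and -8.73, and that of the mirtron miR-1012-3p, also without exact reads in both, was -5.94. The others were miR-959-3p (-6.60), the early-embryo miR-286-3p (-5.02) and miR-986-5p (-4.01). Against D. sechellia alone miR-986-5p stood at -2.57 and, with under 100 reads in each of those 3 libraries, miR-286-3p at -2.04 and, at the floor, miR-976-3p at -3.45 and miR-310-3p at -2.42. With up to 3 mismatches miR-1012-3p had 77 reads in D. yakuba, led by A11G with C16U. In D. erecta it had 702, led by G10U with A11G and C16U. With 1 mismatch miR-959-3p, with U17C in both, had a mean log2 ratio of 1.13. With up to 3 mismatches miR-962-5p turned: 300, 275, 558 and 730 RPM in D. simulans, D. sechellia, D. yakuba and D. erecta. In that order miR-976-3p stood at 151, 5.84, 30.3 and 27.8, miR-963-5p at 25.3, 31.8, 11.01 and 26.6, and miR-310-3p at 16.3, 2.74, 4.68 and 8.96. If the reads with mismatches came from the same miRNAs, exact matching overstated how low these testis-cluster miRNAs stood. Of 97 miRNAs 33 were at least 2-fold higher in D. yakuba and D. erecta and 23 lower, and against D. sechellia alone 11 of 89 were higher and 11 lower; of the 56 past 2-fold, 20 then had the other sign and 14 were again at least 2-fold with the same sign and at least 100 reads. Per all reads, which moved the median of all by -0.67, 25 miRNAs were higher and 33 lower, and with DESeq2 size factors, by -0.35, 27 and 29.

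Among lists, the K-box miRNAs had 4 of 6 members higher in D. yakuba and D. erecta (median log2 ratio 2.24, percentile 98.02), against 1 of 6 relative to D. sechellia alone, where the median was 0.58; 1 member was also lower per all reads and with DESeq2 size factors. The neural list had 5 of 6 higher and miR-315-5p lower (median 1.84, percentile 91.6), or 4 higher per all reads and with DESeq2 size factors; relative to D. sechellia alone 1 was higher and 1 lower. Both muscle miRNAs were higher (median 3.39), and neither was at least 2-fold different from D. sechellia. The ovary list had 2 of 3 higher (median 4.48, or 3.18 at the floor), and 1 higher and 1 lower against D. sechellia. Of the somatic list 12 were higher and 9 lower of 52 (median -0.03, or 0.04 with TMM scaling); DESeq2 size factors gave 11 and 14 (median -0.38), all reads as denominator 9 and 18 (-0.69), and D. sechellia alone 4 and 2 of 50 (0.23). Of the let-7 cluster let-7-5p was higher (1.24, but under 2-fold per all reads and with DESeq2 size factors, while TMM scaling gave 2 higher), of the miR-277 cluster miR-34-5p was higher (2.98) and miR-317-3p lower (-2.40), and of the further arms miR-276a-5p and miR-8-5p were higher and miR-281-2-5p lower (median 0.57, or -0.10 per all reads), with miR-8-5p at 1.0004 and 1 higher per all reads and with DESeq2 size factors. Against D. sechellia alone no member of either cluster was past 2-fold (let-7-5p 0.18, miR-34-5p 0.35, miR-317-3p 0.33), and of the arms none was higher and miR-276a-5p was lower, with miR-8-5p at -0.26. Both early-embryo miRNAs were lower, as was miR-92b-3p at -1.76, which stood at 1.14 against D. sechellia alone. Of 4 mirtrons 1 was higher and 1 lower (median 0.35, or -0.31 per all reads), with none higher per all reads and with DESeq2 size factors and 2 with TMM scaling, and 1 of 3 each way against D. sechellia alone.

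The testis clusters were listed, from general knowledge, as fast-evolving miRNAs expressed mainly in the male germ line. Bodies were sequenced, so the tissue of origin was not tested for any of these clusters. Their 24 listed members took at most 0.243% of miRNA reads in each species, by exact match and with up to 1 or 3 mismatches. Members outside the list or with a changed seed were not searched, so this is no upper limit for the clusters. How far the species differed in this share depended on the match rule. By exact match the 24 members of 5 clusters made up 0.106% (0.103 to 0.108) in D. simulans, 0.0712% (0.0696 to 0.0728) in D. sechellia, 0.0964% (0.0933 to 0.0997) in D. yakuba and 0.109% (0.107 to 0.111) in D. erecta, and of all reads 0.0343%, 0.0248%, 0.0108% and 0.0433%. In D. erecta and D. yakuba 7 members had any exact read, against 10 in D. simulans and 14 in D. sechellia. Among members found everywhere, miR-312-3p stood at 116, 102, 233 and 171 RPM and miR-964-5p at 41.4, 97.4, 273 and 469, in the order D. simulans, D. sechellia, D. yakuba and D. erecta. By cluster, the miR-959 to miR-964 group took 0.0190%, 0.0445%, 0.0276% and 0.0489%, the miR-972 to miR-979 group 0.0157%, 0.0153%, 0.0431% and 0.0420%, and the miR-310 to miR-313 group 0.0710%, 0.0114%, 0.0258% and 0.0178%. No exact read came from the miR-982 to miR-984 group with miR-303, nor from miR-991 and miR-992, which allows up to 0.434, 0.274, 0.826 and 0.274 RPM of the listed sequences. These limits do not cover changed sequences: with up to 3 mismatches miR-991 stood at 117, 179, 0.275 and 0.0915 RPM. By the same rule miR-992 stood at 0, 3.56, 0 and 0.

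The direction of the list as a whole depended on the match rule. By exact match 7 of its 11 measured members were at least 2-fold lower in D. yakuba and D. erecta than in D. simulans and D. sechellia and 3 higher, with a median log2 ratio of -3.36 (-2.38 at the floor) at the 0.730 percentile of random lists. With 1 mismatch, an alternative fixed before the data were examined, 4 of 14 were higher and 8 lower, with a median of -1.38. When up to 3 mismatches were allowed outside the seed, a rule chosen after the data were examined, 7 of 14 were higher and 2 lower, with a median of 1.002, and the counts with up to 2 were the same. Against D. sechellia alone 2 of 8 were higher and 5 lower by exact match (median -2.95, or -1.65 at the floor), 5 of 12 higher and 5 lower with 1 mismatch (-0.0313), and 8 of 13 higher and 2 lower with up to 3 (1.24). With up to 3 mismatches the share, of miRNA reads counted by the same rule, was 0.147%, 0.0958%, 0.212% and 0.243%, and shuffled control sequences of the 24 members drew 1, 3, 7 and 2 reads against 10384, 10870, 7859 and 27011 for the true ones. For D. sechellia over D. simulans, 4 of 10 members were higher and 3 lower by exact match, at a median of 0.09 (percentile 58.6), or 2 higher and 3 lower at -0.15 with DESeq2 size factors. For D. erecta over D. yakuba 1 of 4 was higher, at a median of 0.41 (percentile 54.8), and all 4 per all reads (2.24).

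**Figure D2:**
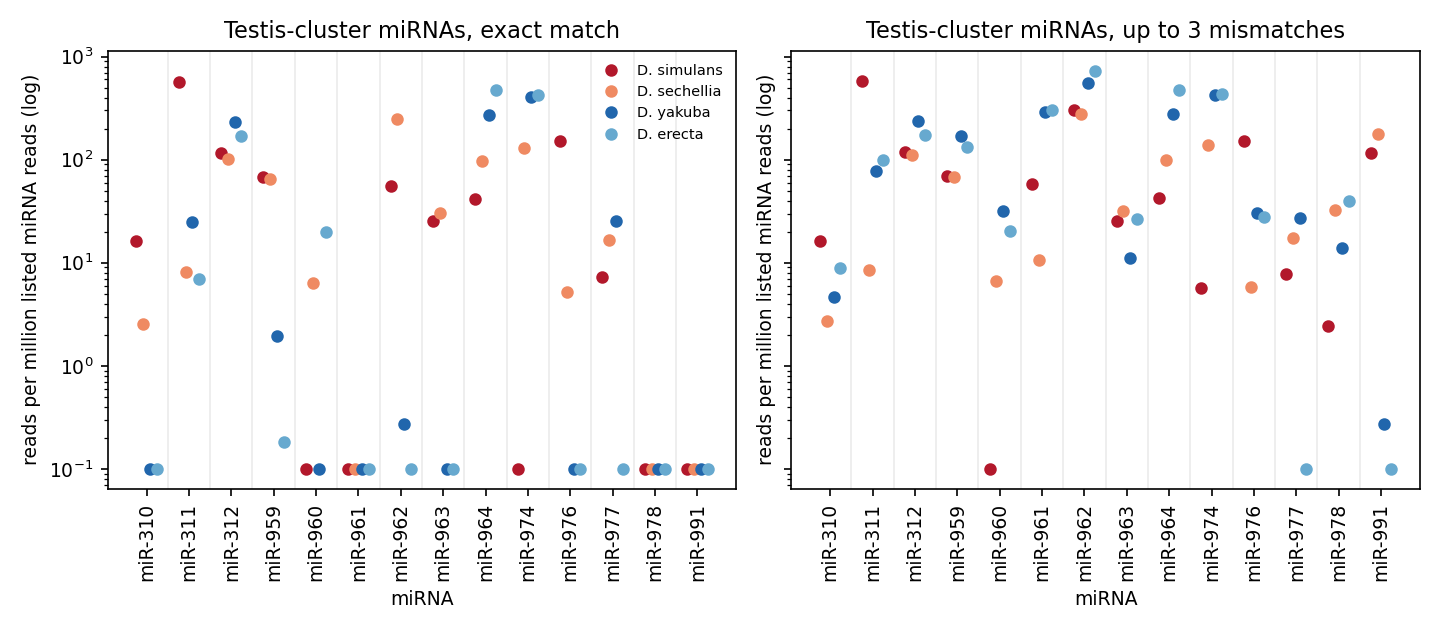
Levels of the testis-cluster miRNAs that reached 100 reads in some library with up to 3 mismatches, in RPM (log axis), by exact match (left) and with up to 3 mismatches in bases 9 to 19 (right), 1 point per library; levels under 0.1 are drawn at 0.1. By exact match miR-962 was absent from D. erecta and had 1 read in D. yakuba, and with mismatches it stood at 730 and 558 RPM there.

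The ovary and early-embryo lists, markers of tissues not expected in male bodies, differed in level between the libraries, as did the neural, miR-92 and mirtron lists. The ovary miRNA miR-989-3p stood at 2.89 RPM (1.77 to 4.47) in D. simulans, 914 (896 to 932) in D. sechellia, 5855 (5777 to 5934) in D. yakuba and 1651 (1627 to 1675) in D. erecta. Of the other ovary miRNAs, miR-318-3p stood at 11.7, 118, 103 and 23.9 and miR-994-5p at 0, 36.03, 64.7 and 19.9. Early-embryo miRNAs summed to 235 RPM in D. simulans, of which miR-286-3p was 203, and to 17.1, 17.9 and 8.96 in the others. Neural miRNAs, expected in the nerve cord of the thorax as well as in the head, summed to 505, 1546, 2285 and 3265, with miR-1000-5p the highest in D. erecta at 1131 and miR-210-3p the highest in D. yakuba at 805. The 2 miRNAs of the miR-92 family summed to 639, 14.6, 71.3 and 12.4, the mirtrons to 137, 187, 361 and 224. Neither the melanogaster Suppressor of Stellate piRNA nor the hairpin siRNA esi-2.1 had an exact read in any library, within the same limits as above. The listed 5′ fragment of tRNA-Gly stood at 21152, 2494, 10020 and 5400 RPM, and that of tRNA-Glu at 236, 264, 872 and 125. RPM is per listed miRNA reads, which were 11.2% of reads in D. yakuba and 39.8% in D. erecta. The orders in this paragraph therefore need not hold per all reads. Reads of the listed tRNA fragments, with shorter pieces of them, made up 1.54%, 0.486%, 0.326% and 0.653% of all reads, with D. yakuba lowest.

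Read lengths peaked at miRNA size in D. simulans, D. sechellia and D. erecta, while D. yakuba held a larger share of longer reads. Reads of 22 and 23 nt made up 38.4%, 40.8% and 41.1% in those libraries and 20.5% in D. yakuba. Reads of 24 to 29 nt, the size of piRNAs (germline small RNAs that silence transposons), were 28.7%, 38.1% and 33.9% and in D. yakuba 51.2%. The highest point of D. yakuba lay at 27 nt with 14.998% of reads, and 9.72% lay at 30 nt, where D. simulans had no read, D. sechellia 0.728% and D. erecta 0.208%. Both values came largely from listed fragments: without reads of 2S rRNA and of the listed tRNA fragments D. yakuba held 8.10% at 27 nt and 0.863% at 30 nt and had its highest point at 22 nt with 13.9%, while its 24 to 29 nt share was 47.8%, against 26.4%, 35.7% and 30.2% in D. simulans, D. sechellia and D. erecta. These shares still hold an unlisted 28 nt fragment of the initiator methionine tRNA, described below. It had 1605 reads with up to 1 substitution in D. simulans, 1992160 in D. sechellia, 1315815 in D. yakuba and 1208929 in D. erecta. It therefore adds to the gap between D. simulans and the others. At 18 nt D. simulans had 7.08%, against 0.389%, 0.728% and 2.18% in D. sechellia, D. yakuba and D. erecta. Among distinct sequences the 24 to 29 nt shares lay closer together, from 39.1% in D. simulans to 47.5% in D. yakuba. The cloning protocols cut different sizes, 18 to 26 nt and 18 to 29 nt. These length differences therefore cannot be told apart from a difference in protocol.

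**Figure D3:**
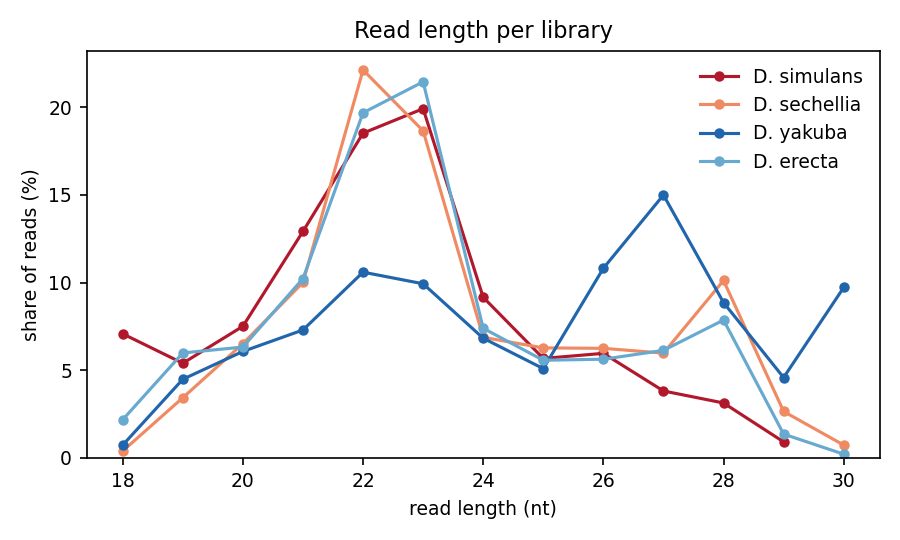
Share of each library's reads (vertical axis, %) by read length in nt (horizontal axis), 1 line per library and species. D. simulans, D. sechellia and D. erecta peak at 22 or 23 nt, and D. yakuba peaks at 27 nt with 14.998%, or at 22 nt with 13.9% when 2S rRNA and listed tRNA fragments, which are included here, are left out.

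Small interfering RNAs cut by Dicer-2 from double-stranded RNA are 21 nt long and leave pairs that overlap by 19 bases with 2 nt overhangs. In D. sechellia 2.79% (2.77 to 2.81) of 21 nt reads outside the list had such a partner, against 0.749% (0.735 to 0.764) in D. erecta, 0.346% (0.337 to 0.355) in D. simulans and 0.0819% (0.0779 to 0.0860) in D. yakuba. Reads of 22 nt with the same 19-base overlap stood at 0.327%, 0.103%, 0.0874% and 0.0208%, in the same order. The 19-base overlap was not set apart from overlaps of 15 to 21 bases: its share over the mean of the others was 1.05, 1.25, 1.11 and 0.592, and in each library some other overlap was higher: 15 bases in D. sechellia (3.13%), 20 in D. erecta (0.888%), and 16 in D. simulans (0.562%) and D. yakuba (0.209%). When all libraries were thinned to 1310755 reads of 21 nt, the shares were 2.44%, 0.749%, 0.323% and 0.0677%.

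A 5′ uridine is a mark of piRNAs bound by Piwi. Among the piRNA-size reads outside the list, a first U was found in 18.3% in D. simulans, 13.8% in D. sechellia, 14.0% in D. yakuba and 13.4% in D. erecta. These reads include the 28 nt initiator tRNA fragment, which begins with A and was nearly absent from D. simulans. At 28 nt a first A was found in 74.8% of such reads in D. sechellia and 29.3% in D. simulans. The shares by reads therefore do not compare piRNAs alone. Among distinct sequences the first U shares were 20.9%, 21.7%, 26.4% and 22.2%, compared with 19.4%, 19.96%, 18.1% and 16.2% among those of 18 to 20 nt. At 21 nt the share was 24.4% in D. simulans, 25.3% in D. sechellia and 19.9% in D. yakuba. At 22 nt it was 22.4% in D. simulans and 24.5% in D. sechellia. In D. simulans and D. sechellia the piRNA-size share thus lay below both, and a first U did not set that class apart. In D. yakuba the share reached 30.2% at 26 nt. An A at base 10 can be left by the ping-pong cycle of germline piRNAs. It was found in 26.3%, 24.4%, 25.9% and 24.6% of distinct sequences. Among distinct sequences without a first U the values were 26.2%, 24.4%, 25.7% and 24.7%. Distinct unlisted sequences of 20 nt had it in 24.8%, 24.9%, 25.9% and 24.9%, and those of 22 nt in 25.3%, 25.2%, 25.9% and 25.8%. The piRNA-size share was above both in D. simulans only, so these shares alone do not show a ping-pong trace.

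Most distinct piRNA-size sequences were read in 1 library, whereas most reads came from sequences found in several. With each library thinned to 21286502 reads, 81.7%, 76.3%, 82.6% and 76.6% of the distinct 24 to 29 nt sequences of D. simulans, D. sechellia, D. yakuba and D. erecta were found in no other library. Absence partly reflects sampling, since most sequences were read once: among those read at least 2 times the shares were 67.5%, 53.5%, 62.7% and 50.8%, and by the first 18 bases 56.5%, 47.03%, 63.7% and 56.8%. By library pair, 13.4% of the distinct 24 to 29 nt sequences of D. simulans were identical in D. sechellia, 10.2% in D. erecta and 9.36% in D. yakuba. For D. sechellia the order was D. erecta (14.8%), D. yakuba (13.3%) and D. simulans (11.2%). Of those of D. erecta 15.9% were found in D. sechellia and 14.6% in D. yakuba, and of those of D. yakuba 11.7% in D. erecta, 11.5% in D. sechellia and 6.75% in D. simulans. These orders depended on the setting: by the first 18 bases more D. erecta sequences were found in D. yakuba (34.4%) than in D. sechellia (32.9%), and D. sechellia sequences in D. erecta, D. simulans and D. yakuba at 40.5%, 39.9% and 39.6%; D. yakuba sequences were found more in D. sechellia than in D. erecta without thinning (10.84% and 10.58%) and among those read at least 2 times (27.1% and 27.05%). By reads, between 74.4% (D. simulans found in D. yakuba) and 90.4% (D. yakuba found in D. erecta) of the class was shared. Those reads include 2S rRNA, tRNA fragments and listed miRNAs. Without listed RNAs the same pairs stood at 69.2% and 85.9%, with the initiator tRNA fragment still included. The shares by reads therefore do not describe piRNAs alone. At 22 to 23 nt the distinct shares ran from 8.64% (D. yakuba found in D. simulans) to 17.3% (D. erecta found in D. sechellia).

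Among sequences outside the list, the most abundant in D. sechellia, D. yakuba and D. erecta was 28 nt long, with 1229952, 822361 and 751935 reads, and a variant of it with 1 substitution, of the same length, had 479499, 312584 and 299023 reads. In D. simulans the first 5 had 533450 reads (23 nt), 439404 (21 nt), 175548 (26 nt), 171250 (24 nt) and 167971 (21 nt). The rest of the first 5, of which the 19 nt sequence of D. erecta ranked above that variant, held 269673 reads (22 nt), 124862 and 95156 (both 29 nt) in D. sechellia, 297507 (21 nt), 247812 (24 nt) and 242264 (29 nt) in D. yakuba, and 302049 (19 nt), 99717 (22 nt) and 84670 (24 nt) in D. erecta.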

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

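All tests in this part were chosen after the result was seen. Outside the list, a signal came from the 5′ end of the initiator methionine tRNA, AGCAGAGTGGCGCAGTGGAAGCGTGCTG, whose first 18 bases began 0.00549% of reads in D. simulans, 4.32% in D. sechellia, 3.24% in D. yakuba and 3.05% in D. erecta. Position 9 of this 28 nt fragment, counted from 1 at its 5′ end, was substituted in 28.5% (26.3 to 30.7), 33.3%, 32.7% and 34.1% of the reads with up to 1 substitution. The median over the other positions was 0.0623%, 0.0932%, 0.0743% and 0.0662%.

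For that position, a sequencing error at cycle 9 is argued against by abundant miRNAs, whose rate at position 9 reached at most 0.334% in any library. Copying past a modified base may be the source, since tRNAs often carry a methylated guanosine there: G9A, G9C and G9U all occurred in every library, the rarest at 4.40% of reads, and a base was also missing there or at the identical next position in 3.31% to 5.70%. G9U made up 72.3%, 72.6% and 72.5% of the substituted reads in D. sechellia, D. yakuba and D. erecta, and 45.1% in D. simulans. Gene copies with other bases at position 9 stay open without a genome, since the substituted share ranged over only 5.64 percentage points between species.

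The D. simulans miRNA profile stood apart from the other 3. Evolutionary distance is argued against as the only source, since r of D. sechellia with D. yakuba exceeded r with its sister D. simulans by 0.322 (0.205 to 0.452 over resampled miRNAs). These are the correlations that showed the pattern, so their difference is no separate test. A lower share of muscle RNA is argued against as the only source, since the miR-1 fold was 393 times the miR-133 fold (357 to 434). Both folds had been seen before, and a part played by muscle share is not excluded, since miR-133-3p was also lower in D. simulans. A difference in transcription and a sequence-dependent difference in library preparation cannot be told apart by the median over 13 pairs of miRNAs or arms taken, from general knowledge, to share a transcript: their log2 ratios disagreed by a median of 4.30, at the 66.5 percentile of random pairs, but those of the other library pairs (0.626 to 0.696) also lay within their random pairs (percentiles 17.7 to 24.8), so the test does not show shared transcription where it is expected. That disagreement was 6.18 times the largest among the other library pairs (1.92 to 9.38 over resampled pairs, which reaches under the bound of 2 set for excluding transcription), random pairs rose 3.97 times as well, and 6 of the 13 went at least 2-fold in opposite ways, against at most 1 elsewhere. Which cloning protocol each library had is not given, and a species difference in miRNA stability or processing stays open too, as untested. Read lengths set D. simulans apart as well. In D. simulans 7.86% of reads had 27 nt or more, against 19.5%, 38.2% and 15.6% in D. sechellia, D. yakuba and D. erecta. At 18 nt D. simulans held 7.08%, against 0.389%, 0.728% and 2.18%. Without knowing the protocols, such lengths cannot tell preparation from species.

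Of 16 testis-cluster miRNAs with at most 1 exact read in D. yakuba and D. erecta together, 5 were picked for having at least 20 reads in D. simulans or D. sechellia (miR-310, miR-313, miR-962, miR-963 and miR-976); the other 11 had at most 2 exact reads in D. sechellia and none in D. simulans. For the 5, sequencing depth is argued against: the D. sechellia level predicted at least 10.6 reads in both libraries together. That lowest value was for miR-313, from 8 reads in D. sechellia. Its lower limit of 4.59 was little above the upper limit of 3.69 for the 0 reads found. For miR-962 3586 were predicted, where 1 was read. The 5 were picked for few reads in D. yakuba and D. erecta, so this comparison is no separate test. Depth is also argued against for 4 of those 11, since with up to 3 mismatches miR-961 (1062 and 3329) and miR-978 (51 and 431) were read in D. yakuba and D. erecta, and miR-991 and miR-992, with 1958 and 39 reads in D. sechellia, fell below the lower limits expected there; the other 7 had at most 4 reads in any library, so depth stays open for them. A diverged sequence missed by an exact match is a candidate explanation: 4 of the 5 had at least 50 reads with up to 3 mismatches there, such as 10009 for miR-962, where the shuffled control had 0. For miR-313, 2 such reads were found, and loss of the gene or of its expression stays open. The shuffled control kept the seed, so it cannot tell a diverged miRNA from another miRNA with the same seed.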

How the results depend on the processing

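Values follow the order D. simulans, D. sechellia, D. yakuba, D. erecta, and the cause of a change was not tested except where named; settings chosen after the data were examined are the contrast without D. simulans, 3 mismatches, the wider 5′ start, the denominator without 2S and thinned 21 nt reads. No paired analysis was possible because each species has 1 library, so no replicate could be left out either. Counts of miRNAs past 2-fold stayed within 1.5 times in D. sechellia over D. simulans under every setting run. In D. erecta over D. yakuba 78 were higher and 0 lower per all reads, 74 and 1 per reads without 2S, both because D. yakuba had fewer miRNA reads; 11 were higher with DESeq2 size factors, and 10 lower with a minimum of 20 reads and 14 with none, where more miRNAs are counted. Without D. simulans the third contrast gave 11 higher and 11 lower. Of 511 values under the alternatives, without the 3-mismatch rule, of the miRNAs with the highest and lowest ratios of each contrast (not of other list members), 9 changed sign. They were miR-994-5p (0.13) and miR-999-3p (0.59, and 0.29 without 2S) per all reads and miR-274-5p (-0.22) at the listed start, where nearly no read began, in D. erecta over D. yakuba; miR-960-5p (-0.63) and, in the third contrast, miR-959-3p (1.13) with 1 mismatch; and miR-1-3p (-0.0504), miR-994-5p (-0.0033) and miR-276a-5p (-1.32) without D. simulans. Of all 97 miRNAs measured in the third contrast 40 changed sign without D. simulans, 20 of them past 2-fold before, among them miR-92b-3p (1.14) and miR-317-3p (0.33). With 3 mismatches, not counted among the 511 values, miR-962-5p also turned. Its exact-match ratio in the third contrast was -9.73, and it then stood at 300, 275, 558 and 730 RPM.

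The testis-cluster share in percent was 0.0343, 0.0248, 0.0108 and 0.0433 of all reads, 0.117, 0.0924, 0.170 and 0.126 with 1 mismatch, 0.147, 0.0958, 0.212 and 0.243 with 3, 0.111, 0.0764, 0.0998 and 0.112 at the listed start, 0.0347, 0.0598, 0.0707 and 0.0910 without the miR-310 group, and 0.159, 0.103, 0.135 and 0.153 without each library's leading miRNA; D. yakuba was highest with 1 mismatch and D. erecta with 3. The 24 to 29 nt share was 39.1, 42.9, 47.5 and 41.1% of distinct sequences, 26.4, 35.7, 47.8 and 30.2% without 2S and listed tRNA fragments and 28.2, 37.9, 51.3 and 33.6% without sequences read once, with D. yakuba highest throughout. The unlisted initiator tRNA fragment, nearly absent from D. simulans, was left in under each of these settings. The duplex share was 0.596, 2.18, 0.230 and 0.459% of distinct sequences, 0.0861, 1.94, 0.0235 and 0.559% without sequences read once, 0.181, 1.19, 0.0525 and 0.434% at 20 to 22 nt and 0.323, 2.44, 0.0677 and 0.749% when thinned; D. sechellia was highest and D. yakuba lowest in each. The first U share was 18.2, 15.1, 16.3 and 14.3% at 24 to 26 nt, 15.4, 14.96, 16.7 and 15.3% at 25 to 27 nt, 20.9, 21.7, 26.4 and 22.2% of distinct sequences and 18.1, 13.3, 13.2 and 12.7% without sequences read once, so which library led depended on the setting. Sharing of 24 to 29 nt sequences, for D. simulans in D. sechellia, D. erecta in D. yakuba and D. sechellia in D. yakuba, was 25.7%, 31.4% and 26.9% for sequences read at least 2 times, 15.1%, 15.1% and 12.97% without thinning, 35.5%, 34.4% and 39.6% by the first 18 bases and 13.3%, 14.4% and 13.1% without listed RNAs. Per 1000000 reads of the library miR-989-3p stood at 0.940, 318, 657 and 657. Depth limits miRNAs under 100 reads, and a zero is taken at the floor of 3 reads per library.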

Other observations

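The counts in this part were chosen after the data were examined. Among miRNAs with at least 50 reads (up to 3 mismatches in bases 9 to 19) in 2 or more libraries, the leading sequence differed between libraries for 9 of 14 testis-cluster miRNAs and for 2 of 85 others, miR-79 and the mirtron miR-1012. Substitutions are given against the listed D. melanogaster sequence, counted from 1 at its 5′ end, and changes in the seed were not searched. D. yakuba and D. erecta shared U17C in miR-959, A11G with A14U in miR-961, A12C with C17U in miR-976, A14U with A15G in miR-978 and A13C with G16A in miR-311. In miR-962 A18U led in D. yakuba, G11A with A18U in D. erecta, and A10C with G17C and A18C in D. simulans, where 18.4% of reads kept the listed sequence, against 89.4% in D. sechellia. In miR-961 D. sechellia carried C16G and D. simulans C9U with C16G. A miR-991 with U10A had 1958 reads in D. sechellia and 807 in D. simulans, against 1 read each in D. yakuba and D. erecta.

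The 5′ ends of some miRNAs, which set the seed, also differed between libraries. Reads of miR-956-3p beginning 1 base downstream of the listed 5′ end were 22.8% in D. simulans, 27.9% in D. sechellia, 33.8% in D. yakuba and 51.1% in D. erecta. For miR-210-3p, reads beginning 1 base upstream were 64.5%, 42.6%, 43.7% and 64.5%, and for miR-281-3p 67.8%, 35.6%, 42.2% and 51.9%.

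Unlisted 21 nt reads of D. sechellia were richer in sequence from both strands than those of the other libraries. Of the 17-base words read at least 2 times, 4.84% were also read at least 2 times as their reverse complement, against 1.41% in D. simulans, 0.553% in D. yakuba and 1.18% in D. erecta. The excess was not particular to that length: at 20 nt the shares were 1.84% in D. sechellia and 0.241%, 0.0352% and 0.297% in the others, at 22 nt 2.17% and 0.299%, 0.0937% and 0.258%, and at 23 nt 0.650% and 0.182%, 0.0724% and 0.142%. At 25 nt the shares were 0.212%, 0.186%, 0.285% and 0.276%, with D. sechellia first.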
